A study of Mus musculus with 6 samples.

How the data were processed

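The samples are 6 RNA-seq libraries of the EO771 mouse mammary carcinoma line, 3 of cancer stem cells (CSC) and 3 of other cells (non-CSC), grouped by their titles. Per the labels, RNA was extracted with Trizol and libraries were made from 1.3 ug of total RNA with a NEBNext Ultra II kit. Whether messenger RNA was selected or ribosomal RNA depleted is not given in the sources used here. The authors deposited 1 table of raw read counts per gene symbol, whole numbers with no normalization, made on GRCm38 per the submitters' processing notes. The aligner, the counting tool, the annotation, the strand setting and any filter are not given in the sources used here. The table holds 49523 gene symbols, and its 6 value columns were matched to the samples by group word and replicate number. All 49523 symbols are in the RefSeq gene table of GRCm38.p6, which gave positions and gene types. No row without a gene name was present.

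Totals ranged from 27099879 to 35971131 counts per library. The counts of 4 small structural RNAs (Rpph1, Rn7s1, Rn7s2 and Rmrp) made up 3.15% to 3.82% of a library, and the 10 highest genes 5.95% to 6.75%. Replicates were compared before averaging. Over genes with at least 20 counts in a pair, the chi-square per degree of freedom between replicates of a group was 3.21 to 7.30, so none agree within sampling noise, and all 6 libraries were kept as separate samples. On the main component of log2 CPM, which held 86.8% of the variance, non-CSC libraries lay between -51.8 and -50.3 and CSC libraries between 50.8 and 51.0. Counts of 0 and low counts carry counting error, and reads without molecular identifiers are not independent molecules.

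From the deposited counts, genes were filtered with edgeR's filterByExpr, which left 17630, and scaled with TMM factors of 0.974 to 1.03. The comparison of CSC with non-CSC was fitted with edgeR's quasi-likelihood test (robust setting on, no covariate), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes. An additional count took genes with a change of at least 2-fold. Sema3c, as the gene of the series title, also had an exact two-sided permutation test of its log2 CPM, which with 3 against 3 libraries cannot go below 0.1.

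Before the data were examined, the design, the alternatives, the 46 gene lists with 1012 entries and the rule for named genes were fixed. Of the entries, 43 were matched through an older or newer symbol. Lists with at least 5 tested members were tested with camera (limma) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 42 lists, and again with an estimated correlation and with fry. The lists are of the kinds described with the results: semaphorins and receptors, stem cell and lineage genes, cell cycle, metabolism, stress, signalling, interferon and inflammation, other cell types, and library quality. The genes named are Sema3c, the 12 largest rises and the 12 largest falls, and up to 4 members of each list. For the rises and falls the rule asked for an adjusted p under 0.05, a mean of at least 5 CPM, groups without overlap and a symbol that is not a predicted or clone name. For the lists it took the members with the largest changes among those with an adjusted p under 0.05 and a mean of at least 5 CPM. Also by the rule, the 5 protein-coding genes on each side of Sema3c are described among the other observations. Some genes that the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

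Overlap was checked for the named genes with the GENCODE M21 annotation and transcripts of GRCm38: exon bases covered by other genes on either strand, and the share of 50-base words of the longest transcript found in transcripts of other genes. Of 180 named genes 171 were matched to an entry by symbol or gene identifier. The mitochondrial genes, among others, were not matched, so their overlap was not checked. GC content and length came from the same transcripts, for 87.3% of the genes tested.

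The alternatives were RLE, upper-quartile and plain library-size scaling, no filter beyond 1 count, a filter at a mean of 50 counts, DESeq2, limma-voom, the robust setting off, leaving out each library, a replicate block with and without an offset for GC content and length, and that offset alone. A chromosome offset was added after the chromosome medians were seen. It takes the median of each whole chromosome, so a shift of only part of a chromosome is not removed by it. The upper-quartile and library-size scalings moved the median log2 fold change of all genes by 0.06 and 0.07. The fit was also repeated for the 10 splits of the 6 libraries into equal groups.

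The method was tested on counts simulated from the real means, spreads and library sizes, for 17307 genes of this comparison. Of 50 genes each changed 1.25-fold, 1.5-fold, 2-fold and 4-fold, 62%, 80%, 96% and 98% were recovered. Of 16514 unchanged genes 41 were called, which made 7.47% of the calls. In the real comparison 11732 of 17630 genes were called, so these rates hold only for data in which most genes are unchanged. With 1 list shifted by -0.5 on the log2 scale, 1 list was called. Genes were drawn independently of each other, so list calls among correlated genes were not tested by it. A chromosome shifted by -0.3 had a median of -0.29, and no other chromosome of at least 100 genes lay farther from 0 than 0.009. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15 were used.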

Results

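RNA sequencing was done on EO771 cells, a mouse mammary carcinoma line, which the labels divide into cancer stem cells (CSC) and cells that are not (non-CSC). Each group had 3 libraries, and the values are read counts per gene symbol. The non-CSC libraries held 32204112, 35646676 and 35971131 counts, and the CSC libraries 27099879, 27703610 and 28205651. The labels do not say how the CSC were obtained or whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The series title concerns a LINE-1 element that acts as an enhancer of Sema3c, and the design text names a single comparison, CSC against non-CSC, which asks which genes differ in expression between the groups.

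Sema3c, which encodes a secreted class 3 semaphorin, was higher in CSC. It lies on chromosome 5 at 17574816 to 17730268 (GRCm38) and is protein-coding. Its level was 147 ± 2.21 CPM in non-CSC (SD, n = 3) and 585 ± 17.3 CPM in CSC (SD, n = 3), a 3.97-fold difference. The log2 fold change was 1.99 with a standard error of 0.037 (edgeR adjusted p = 2.88e-22). The counts behind it were 4582, 5068 and 5298 in the non-CSC libraries and 15641, 17041 and 17008 in the CSC libraries. An exact two-sided permutation test of the 6 log2 CPM values gave p = 0.1, the smallest that 20 assignments allow.

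Other semaphorin genes and their receptors moved in the same comparison. Of the class 3 semaphorins, 5 were tested; 4 rose and 1 fell, with a median log2 fold change of 0.79, and the list as a whole did not pass the test against other genes (camera adjusted p = 0.102), though it did without a low-count filter (adjusted p = 0.0378). Sema3f rose by 0.79 and Sema3b by 0.43 on the log2 scale. Of the neuropilins and plexins, the receptors and co-receptors of semaphorins, 9 of 11 rose and 2 fell, with a median of 0.51 (camera adjusted p = 0.0166; adjusted p = 0.325 with an estimated correlation). Nrp1 rose from 2.72 ± 0.119 CPM to 30.5 ± 0.374 CPM (SD, n = 3 each), a log2 fold change of 3.49 ± 0.074 (SE), and Plxna2 from 17.8 ± 0.364 to 60.1 ± 1.83 CPM. Plxna3 rose by 0.50 and Plxnb2 by 0.45 on the log2 scale. Nrp2, chosen after its value was seen, fell by 0.12, a call lost with upper-quartile and library-size scaling. The call of the receptor list was lost when only genes with a mean of 50 counts or more were tested (camera adjusted p = 0.0741).

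**Figure D1:**
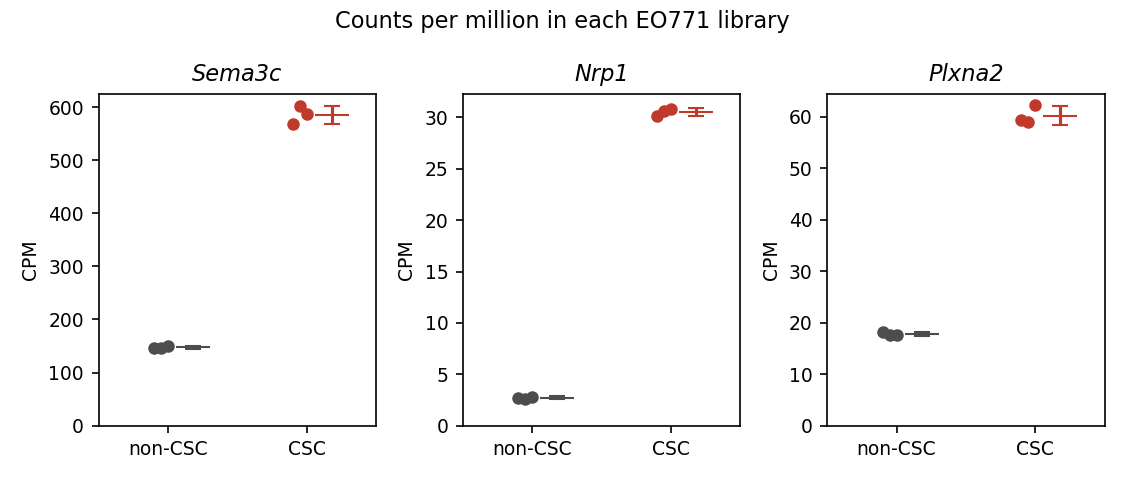
CPM of Sema3c, Nrp1 and Plxna2 in each library, with points for libraries and bars for the mean and SD of 3 libraries per group. Sema3c lay at 147 CPM in non-CSC and 585 CPM in CSC, and all CSC libraries lay above all non-CSC libraries for the 3 genes.

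Across the transcriptome, 17630 genes were tested and 11732 differed between the groups at an adjusted p under 0.05 (edgeR quasi-likelihood test), 5894 higher and 5838 lower in CSC. Which direction held more genes depended on the scaling and the model. At least 2-fold changes were found for 2134 genes, 1413 higher and 721 lower. When only genes with a mean of 50 counts or more were tested, these were 1088, 644 higher and 444 lower. Of the 12602 protein-coding genes tested, 9322 differed. The spread within groups was small, with a common biological coefficient of variation of 4.11%, which lets small differences pass the test. The log2 CPM values of libraries correlated across genes at r = 0.9958 to 0.9966 within groups and 0.9642 to 0.9651 between groups; genes are not independent replicates.

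Among the 12 largest rises, Lcn2, a secreted iron-siderophore binding protein, rose by 7.10 on the log2 scale, from 0.109 to 15.4 CPM. The chemokine gene Cxcl5 rose from 2.74 to 58.2 CPM, and Enpp2, which encodes autotaxin, from 6.38 to 118 CPM. Greb1, known as an oestrogen-responsive gene, rose from 1.76 to 80.4 CPM, and the guanine deaminase gene Gda from 0.258 to 14.6 CPM. Xist, the long non-coding RNA of X inactivation, rose from 6.30 ± 0.303 to 206 ± 7.15 CPM (SD, n = 3 each), and the counts assigned to its antisense partner Tsix from 0.490 to 17.97 CPM. Because the strand setting of the counting is not given in the sources used here, reads from bases that Xist and Tsix share cannot be told apart. Exons of Xist cover 32.6% of those of Tsix. Cdyl2, Rasl10b, Gng4 and Gbp9 had log2 fold changes of 5.19, 4.92, 4.36 and 4.24.

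The 12 largest falls included several genes of amino acid stress and of the interferon response. Trib3, a pseudokinase induced under stress, fell by 4.54 on the log2 scale, from 174 ± 3.04 to 7.47 ± 0.275 CPM (SD, n = 3 each). Slc7a11, the cystine-glutamate exchanger, fell from 131 to 7.57 CPM, and Chac1, a glutathione-degrading enzyme, from 42.0 to 3.36 CPM. Stc1, which encodes stanniocalcin 1, fell from 121 to 7.71 CPM, and Tnc, which encodes the matrix protein tenascin C, from 16.4 to 1.07 CPM. Oas3, an interferon-induced oligoadenylate synthetase, fell from 48.4 to 3.30 CPM, and Ifi27l2a, another interferon-induced gene, from 20.01 to 1.65 CPM. Sema7a, a membrane-anchored semaphorin, fell from 21.1 to 1.92 CPM. Ctag2l1 fell by 5.49, Ksr2 by 3.77, Blnk by 3.63 and Selenbp1 by 3.45 on the log2 scale. Selenbp1 shares 52.3% of its 50-base words with its paralog Selenbp2, and Ctag2l1 was not matched to the transcripts used, so both levels are uncertain. The highest edgeR adjusted p among the 23 genes given here was 3.07e-16, that of Ctag2l1.

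**Figure D2:**
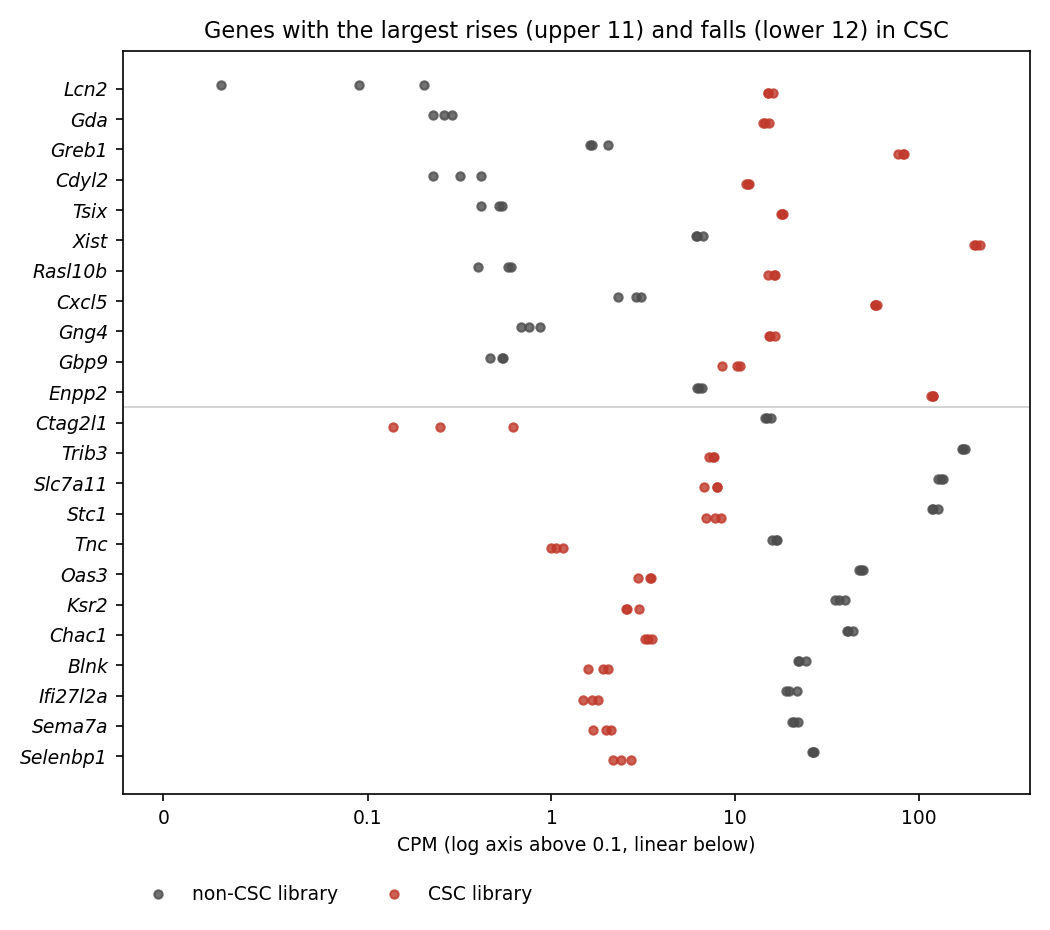
CPM (log axis above 0.1, linear below) of 11 genes with the largest rises and 12 with the largest falls, with 1 point per library. Groups do not overlap for any of the 23 genes, which the naming rule required; Xist lay near 6.30 CPM in non-CSC and 206 CPM in CSC, and Trib3 near 174 and 7.47 CPM.

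Of 46 gene lists fixed before the data were examined, 42 had at least 5 tested members. By camera, which sets a list against all other genes, 11 lists were shifted, 3 higher and 8 lower in CSC. With an estimated correlation in place of the preset 0.01 none of the 42 passed, and 7 had an unadjusted p under 0.05. By fry, which asks whether the members move in 1 direction on balance without comparing them with other genes, 39 passed, the 11 among them. Counts of members adjusted over the list alone equalled those over all genes tested in 39 of the 46 lists and are given beside the other 7. Some genes are members of several lists, for example Slc7a11 (stress response and antioxidant lists) and Lgr5 (stem cell, basal and Wnt lists), so the lists are not independent.

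Targets of ATF4, the transcription factor of the integrated stress and amino acid response, were lower in CSC throughout. All 23 tested members fell, 15 of them at least 2-fold, with a median log2 fold change of -1.37 (camera adjusted p = 5.91e-13; adjusted p = 0.0746 with an estimated correlation). Besides Trib3, Slc7a11 and Chac1, the stress transcription factor gene Ddit3 (CHOP) fell from 58.0 to 9.81 CPM. Atf4 itself, chosen after its value was seen, fell from 329 to 95.3 CPM. Targets of NRF2 and antioxidant enzymes were also lower, with 17 of 23 lower, 3 higher and a median of -0.37 (camera adjusted p = 0.000544; adjusted p = 0.192 with an estimated correlation). Nqo1, a quinone reductase, fell by 1.45, Osgin1 by 1.29 and the glutathione transferase gene Gstm1 by 1.23 on the log2 scale.

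Genes induced by low oxygen and genes of sugar breakdown were lower in CSC. Of 21 tested HIF targets, 19 fell and none rose, with a median of -0.76 (camera adjusted p = 4.27e-07; adjusted p = 0.0746 with an estimated correlation). Ndrg1 fell from 376 to 74.9 CPM, the oxidoreductase gene Ero1a from 280 to 79.0 CPM, the angiogenic factor gene Vegfa from 195 to 61.2 CPM and Bnip3, a mitophagy receptor, from 151 to 57.6 CPM. Of 20 glycolysis genes, 16 fell and 3 rose, with a median of -0.55 (camera adjusted p = 0.000707; adjusted p = 0.347 with an estimated correlation). Aldoc fell by 1.45, the pyruvate dehydrogenase kinase gene Pdk1 by 1.18, the glucose transporter gene Slc2a1 by 0.91 and Pgk1 by 0.86 on the log2 scale. Cholesterol synthesis genes and SREBP2 targets were lower as well, 17 of 24 (18 adjusted over the list alone) with 3 higher and a median of -0.29 (camera adjusted p = 0.00256; adjusted p = 0.151 with an estimated correlation). Msmo1 fell by 1.58, Fdft1 by 1.04 and the regulator gene Srebf2 by 0.99 on the log2 scale, while Hsd17b7 rose by 1.42.

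Mitochondrially encoded protein genes were higher, 10 of 13 with none lower and a median of 0.48 (camera adjusted p = 0.0345; adjusted p = 0.398 with an estimated correlation). COX3 rose from 640 ± 28.8 to 991 ± 49.3 CPM (SD, n = 3 each) and ND3 by 0.86 on the log2 scale. These genes took 0.282% to 0.287% of counts in the non-CSC libraries and 0.345% to 0.366% in the CSC libraries. The list was fixed as a measure of library quality. Its shift cannot tell library composition from a difference between the cells. The list's call was lost without non-CSC replicate 1 (camera adjusted p = 0.0678) and without CSC replicate 3 (camera adjusted p = 0.0596). Nuclear-encoded respiratory chain subunits did not pass as a list, with 11 of 33 higher, 14 lower and a median of -0.02 (camera adjusted p = 0.529). Among them Ndufb5 fell by 0.72 and Ndufb8 by 0.60 on the log2 scale. Both lie in stretches that were lower as a whole. The 30 adjacent tested genes that hold Ndufb5 on chromosome 3 had a median -0.515 from that of all genes. Those that hold Ndufb8 on chromosome 19 had -0.423. Fatty acid genes were split, with 8 of 22 higher, 8 lower and a median of -0.02 (camera adjusted p = 0.961). Acsl1 rose by 0.81 and Elovl5 by 0.79, while Fabp5 fell by 0.82 and Acadm by 0.74 on the log2 scale.

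Interferon-stimulated genes were lower in CSC for the larger part. Of 32 tested, 23 fell, 17 of them at least 2-fold, and 5 rose, with a median of -1.11 (camera adjusted p = 0.000235; adjusted p = 0.111 with an estimated correlation). The regulator gene Irf7 fell from 37.4 to 6.03 CPM and Oasl2 from 11.8 to 3.72 CPM. NF-kB targets, cytokines and chemokines included 13 of 23 higher and 6 lower, with a median of 0.38, and did not pass as a list (camera adjusted p = 0.102), though they did under 2 of 15 alternatives of scaling, filter, offset and libraries. Besides Lcn2 and Cxcl5, the cytokine genes Csf2 and Ccl2 rose by 2.25 and 1.87 on the log2 scale. The genes of MHC class I presentation did not pass either, with 7 of 16 higher, 4 lower and a median of 0.38 (camera adjusted p = 0.449). Cd274, which encodes the checkpoint ligand PD-L1, fell from 29.2 to 5.01 CPM, while the immunoproteasome genes Psmb10 and Psmb8 rose by 1.33 and 1.17 and the peptidase gene Erap1 by 1.12 on the log2 scale.

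Cell cycle genes moved in different directions. Of 30 mitotic genes, 21 fell and 2 rose, with a median of -0.25 (camera adjusted p = 0.000927; adjusted p = 0.133 with an estimated correlation). Ect2 fell by 0.74, the cyclin gene Ccna2 by 0.69, the checkpoint kinase gene Bub1b by 0.63 and Cdca8 by 0.58 on the log2 scale. The 30 adjacent tested genes of chromosome 3 that hold Ccna2 had a median -0.515 from that of all genes. DNA replication genes included 17 of 29 higher (18 adjusted over the list alone) and 6 lower, with a median of 0.23 (camera adjusted p = 0.0519), and passed as a list under 4 of 15 alternatives. The cyclin gene Ccne1 rose by 0.77 and Tyms by 0.66 on the log2 scale. Replication-dependent histone genes, a list fixed for library quality, included 1 of 22 higher and 11 lower, with a median of -0.20 (camera adjusted p = 0.0806). They passed as a list under 3 of 15 alternatives. H4c9 fell by 0.51 and H2ac18 by 0.38 on the log2 scale, and H1f0, a linker histone gene on the list that is known to be expressed outside replication, fell by 0.61. CDK inhibitors and quiescence genes were split, with 6 of 17 higher, 8 lower and a median of -0.03 (camera adjusted p = 0.346). Foxo1 fell by 1.28, Hes1 by 1.17, Ccng2 by 1.03 and Btg1 by 0.96 on the log2 scale.

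Immediate early genes were lower in CSC, 17 of 23 with 2 higher and a median of -0.73 (camera adjusted p = 0.000544; adjusted p = 0.398 with an estimated correlation). The transcription factor genes Fosl1 and Egr1 fell by 1.68 and 1.67 and the phosphatase gene Dusp5 by 1.34 on the log2 scale, while Ier3 rose by 1.67. Targets of p53 were higher, 15 of 23 with 4 lower and a median of 0.38 (camera adjusted p = 0.0292; adjusted p = 0.244 with an estimated correlation). Ddit4l rose by 1.46, Phlda3 by 1.24 and Eda2r by 1.14, while Sesn2, which is also an ATF4 target, fell by 1.38 on the log2 scale. The p53 call was lost under a replicate block with a GC content and length offset (camera adjusted p = 0.0527).

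**Figure D3:**
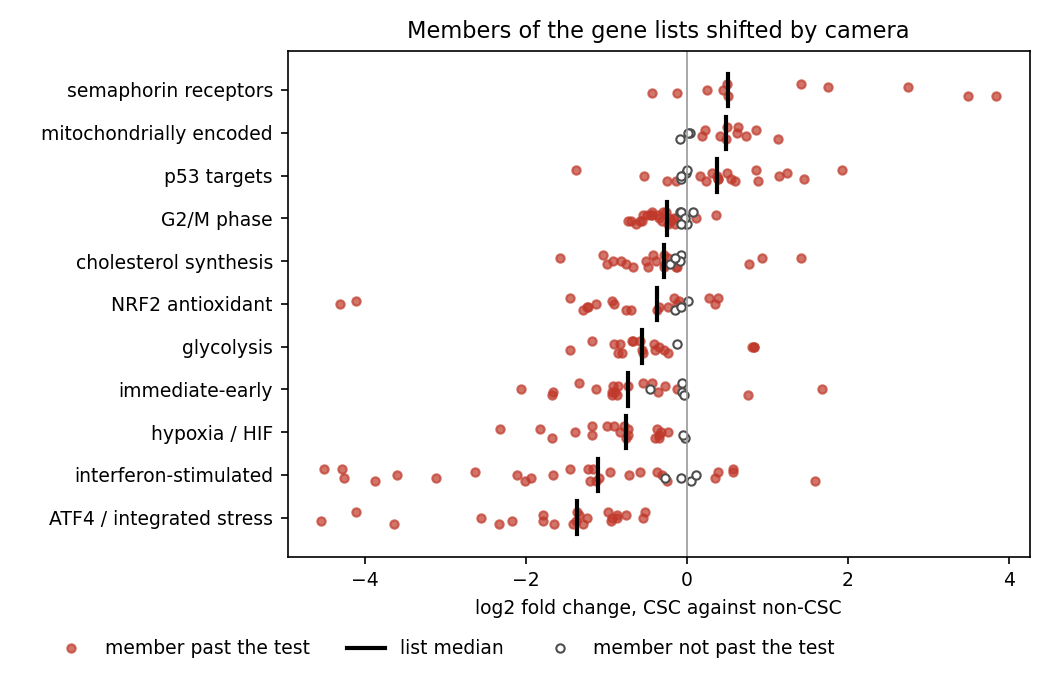
Log2 fold changes, CSC against non-CSC, of the tested members of the 11 lists shifted by camera, with filled points for members past the test, open points for others and a bar at the list median. Medians ran from -1.37 for ATF4 targets to 0.51 for semaphorin receptors.

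Markers used to define breast cancer stem cells did not pass as a list. Of 17 tested, 10 rose, 6 of them at least 2-fold, and 5 fell, none of them 2-fold. The median was 0.17 (camera adjusted p = 0.112). The aldehyde dehydrogenase gene Aldh3a1 rose by 1.68, the R-spondin receptor gene Lgr5 by 1.29, the efflux pump gene Abcb1a by 1.19 and Tspan8 by 1.15 on the log2 scale. Chosen after their values were seen, Aldh1a1 rose from 487 to 785 CPM and Cd44 from 689 to 774 CPM, while Itga6 fell from 1449 to 847 CPM. Pluripotency factors included 2 of 6 higher and 2 lower (camera adjusted p = 0.843); their median of -0.02 and mean of 0.33 differ in sign. Tfcp2l1 rose by 2.16 and Tbx3 by 0.37, and Klf2 fell by 0.35 and Klf4 by 0.18 on the log2 scale. Factors that restrict LINE-1 and other retroelements were split, with 9 of 25 higher, 9 lower and a median of 0.06 (camera adjusted p = 0.729). The editing enzyme gene Adar rose by 1.24 and the deaminase gene Apobec3 by 1.03, while Rnaseh2c fell by 0.83 and the DNA methyltransferase gene Dnmt3a by 0.71 on the log2 scale.

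Epithelial, mesenchymal and mammary lineage lists did not pass the test. Epithelial genes included 7 of 19 higher and 6 lower, with a median of -0.03 (camera adjusted p = 0.819). The keratin gene Krt7 rose by 1.08 and Ehf by 0.85, while Epcam fell by 1.05 and Pkp3 by 0.61 on the log2 scale. Mesenchymal genes included 8 of 19 higher and 8 lower (camera adjusted p = 0.729); the median was -0.06, the mean 0.14 and the direction of the test lower. Vim, which encodes vimentin, fell by 0.55 and Loxl2 by 0.54 on the log2 scale, while S100a4 rose by 1.40. Mammary luminal genes included 5 of 9 higher and 3 lower, with a median of 0.15 (camera adjusted p = 0.772), and fry gave the direction lower. The growth factor gene Areg, which encodes amphiregulin, fell from 68.4 to 8.20 CPM, and Krt8 rose by 0.27 on the log2 scale. Mammary basal genes included 6 of 10 higher (7 adjusted over the list alone) and 3 lower, with a median of 0.30 (camera adjusted p = 0.287). Mylk rose by 0.73 and Itgb4 by 0.58 on the log2 scale. Collagens and matrix proteins included 9 of 19 higher and 9 lower, 8 and 3 of them at least 2-fold, with a median of 0.12 (camera adjusted p = 0.83). Thbs1, which encodes thrombospondin 1, rose from 335 to 1535 CPM and Col6a1 by 1.22, while P4ha1, a collagen prolyl hydroxylase subunit, fell by 1.18 on the log2 scale.

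The Wnt, Notch, Hedgehog, TGF-beta, YAP and SRF lists did not pass the test in the main fit; the Wnt, Notch, Hedgehog and SRF lists each passed under 1 of 15 alternatives. Canonical Wnt targets included 9 of 14 higher and 4 lower, with a median of 0.51 (camera adjusted p = 0.102). Notum, a secreted Wnt deacylase, rose from 2.33 ± 0.146 to 38.3 ± 1.68 CPM (SD, n = 3 each), and Nkd1 and Sp5 rose by 1.92 and 1.56 on the log2 scale. Notch ligands, receptors and targets included 2 of 10 higher (3 adjusted over the list alone) and 6 lower, with a median of -0.71 (camera adjusted p = 0.102). The ligand gene Jag1 fell from 336 to 122 CPM, and Notch1 fell by 1.18 and Notch4 by 0.85 on the log2 scale. Hedgehog targets included 4 of 8 higher and 2 lower, with a median of 0.32 (camera adjusted p = 0.215). The co-receptor gene Cdon rose from 21.05 to 141 CPM, and Gli1 rose by 0.82 and Smo by 0.33 on the log2 scale. Ptch1 fell by 0.15, a call lost with upper-quartile and library-size scaling. TGF-beta ligands and targets included 9 of 17 higher and 7 lower, with a median of 0.30 (camera adjusted p = 0.529). Itgb6 rose by 1.83 and Id2 by 0.96, while Ltbp3 fell by 0.82 on the log2 scale. YAP targets included 9 of 21 higher and 10 lower, with a median of -0.06 (camera adjusted p = 0.529). Igfbp3 fell by 1.12, Ankrd1 by 1.06 and Ccn2 by 0.66 on the log2 scale. SRF targets and actin genes included 3 of 15 higher and 10 lower, with a median of -0.21 (camera adjusted p = 0.0806). Tpm2 fell by 1.97, Fhl2 by 1.96 and Actb by 0.48 on the log2 scale.

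Survival and protein homeostasis lists did not pass the test. Anti-apoptotic genes included 5 of 12 higher and 4 lower, with a median of 0.06 (camera adjusted p = 0.843). Bcl2 rose by 0.59 and Xiap by 0.46, while Bcl2l2 fell by 0.66 and Birc5 by 0.43 on the log2 scale. Pro-apoptotic genes included 8 of 18 higher (10 adjusted over the list alone) and 8 lower, with a median of 0.09 (camera adjusted p = 0.957). Bok fell by 1.32 and Bbc3 by 0.53, while Bcl2l11 rose by 0.45 on the log2 scale. The direction by fry was opposite to that by camera for both lists, for the mammary luminal, endothelial and fatty acid lists. Endoplasmic reticulum chaperones and unfolded protein response genes included 5 of 20 higher and 11 lower, with a median of -0.17 (camera adjusted p = 0.215). Sdf2l1 rose by 0.76, while Herpud1 fell by 0.59 on the log2 scale. Cytosolic heat shock genes included 3 of 12 higher and 7 lower, with a median of -0.14 (camera adjusted p = 0.253). Cryab rose by 1.61, while Hsp90aa1 fell by 0.60 on the log2 scale. Lysosome and autophagy genes included 8 of 26 higher and 15 lower, with a median of -0.16 (camera adjusted p = 0.215). Gpnmb fell by 1.20 and the autophagy receptor gene Sqstm1 by 0.98 on the log2 scale. MYC targets of ribosome biogenesis included 9 of 25 higher (10 adjusted over the list alone) and 11 lower (camera adjusted p = 0.924); the median of -0.01 and mean of 0.02 differ in sign. Odc1 fell by 1.19 and Myc itself by 0.86 on the log2 scale. Cytosolic ribosomal protein genes, also a library quality list, included 16 of 43 higher and 9 lower, with a median of 0.07 (camera adjusted p = 0.476). Rps4x rose by 0.63 and Rpl10 by 0.57 on the log2 scale.

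Markers of other cell types were mostly under the count filter in both groups. Of 18 macrophage and myeloid markers 5 were tested, 3 higher and 2 lower, with a median of 0.56 (camera adjusted p = 0.346). Itgam rose from 0.741 to 10.2 CPM and Cd14 by 0.56, while Cd68 fell by 0.51 on the log2 scale. Of 12 neutrophil markers only Lcn2 and Ly6g were tested, and both rose, Ly6g from 2.20 to 9.02 CPM. Of 17 lymphocyte markers 1 was tested, with a log2 fold change of 0.44, which did not pass over all genes and passed adjusted over the list alone. Of 14 endothelial markers 6 were tested, 1 higher and 2 lower (camera adjusted p = 0.926); their median of -0.08 and mean of 0.26 differ in sign. Of 15 fibroblast and pericyte markers 4 were tested and all 4 rose, with a median of 0.91; Dcn, which encodes decorin, rose from 567 to 1212 CPM. Of 14 adipocyte and red cell markers 2 were tested and both rose, with a median of 0.77. No count of C1qa, C1qb, C1qc or Tyrobp was found in any of the 6 libraries.

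Some named genes share bases or sequence with others, and their levels are uncertain for that reason. Of the 171 named genes matched to an entry in the annotation used, 36 share at least 10% of their 50-base words with transcripts of other genes or pseudogenes. Examples are Rps4x (72.2%), Pgk1 (68.0%), Bnip3 (62.4%), Hsp90aa1 (58.5%), Rpl10 (57.2%), Loxl2 (45.8%), Odc1 (42.2%), Fdft1 (30.7%), Krt8 (29.7%) and Gstm1 (23.1%). On the same strand 3 share at least 10% of their exon bases with another gene, Itgam (68.7%), S100a4 (51.7%) and Bcl2l2 (13.3%). Exons on the opposite strand cover at least 10% of those of 22 named genes, among them 57.2% of Fosl1, 38.1% of Notum, 24.8% of Rnaseh2c, 23.2% of Ccn2, 22.3% of Bnip3 and 22.1% of Dusp5.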

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

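The chromosome offset is the 1 alternative chosen after the data were seen. Across 20 alternatives no result changed direction among the named genes and the lists that passed. The balance of calls did turn: 5894 genes were higher and 5838 lower in the main fit, 5836 and 5913 with RLE size factors, 5026 and 5326 with DESeq2, 5431 and 6486 with the GC content and length offset, and 6781 and 4970 with library size alone. Sema3c stayed past the threshold in all that tested it, with a log2 fold change of 1.91 to 2.06 and an adjusted p of at most 1.06e-15. Without a low-count filter 3269 genes changed at least 2-fold, 2236 of them higher, since more low-count genes were tested. With a mean of 50 counts or more, which left 13482 of 17630 genes, these were 1088, 644 higher and 444 lower. They fell by a larger share than the genes tested did, so many of the 2-fold changes, rises above all, lay in genes with lower counts. All other counts of genes lay within 1.5 times those reported. DESeq2 called 10352 genes, limma-voom 11695 and the chromosome offset 11552. Leaving out each library in turn gave 11175 to 11578 changed genes. Of the named genes, 7 lost their call under at least 1 alternative (Nrp2, Ptch1, Esam, ND2, ND4, Pdgfra and Rps7). The count of shifted lists was 0 with an estimated correlation (7 at an unadjusted p under 0.05) and 39 with fry, which tests another question. Semaphorin receptors lost their call with the stricter filter (adjusted p = 0.0741, range over the alternatives of scaling, filter, offset and libraries 0.00337 to 0.0741). Mitochondrially encoded genes lost it without non-CSC replicate 1 (0.0678) and without CSC replicate 3 (0.0596), with a range of 0.0148 to 0.0678. Targets of p53 lost it under the replicate block with the GC content and length offset (0.0527, range 0.0169 to 0.0527). Lists that did not pass in the main fit gained a call as follows. DNA replication genes passed with upper-quartile factors (0.0337), library size alone (0.0341), the stricter filter (0.0242) and without CSC replicate 3 (0.0493). Histone genes passed without a low-count filter (0.00894), without CSC replicate 1 (0.0279) and without non-CSC replicate 3 (0.0481). Without a low-count filter NF-kB (0.0378), Notch (0.033) and class 3 semaphorin (0.0378) lists passed, with the stricter filter Wnt (0.0242) and Hedgehog (0.0473) targets, and with the chromosome offset NF-kB (0.042) and SRF (0.0467) targets. Where not given above, the cause was not tested.

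Replicate numbers are shared between groups. Deviations of same-numbered libraries from their group means correlated across genes at 0.01, -0.05 and -0.003, so no effect shared by same-numbered libraries was seen. Whether they were prepared as pairs cannot be told from this, and the labels do not say. With a replicate block 11680 genes changed. In data simulated at these library sizes, with most genes unchanged, 16 of 26 genes changed 1.5-fold with a mean count under the median of 436.2 were recovered. Above it 24 of 24 were.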

Other observations

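The test of X-linked genes, the tests of abundant transcripts and of markers of other cells and the gene families were chosen after their results were seen, and the other tests of chromosomes and of Xist after those patterns were seen but before the values of the tests were. Genes grouped by the letters of their symbol, with at least 10 tested members, made 156 families; by camera 0 passed after adjustment and 14 had an unadjusted p under 0.05. The 5 with the lowest unadjusted p were as follows. Of 61 Ppp phosphatase subunit genes 33 fell and 7 rose, with a median log2 fold change of -0.16 (camera adjusted p = 0.134). Of 11 Abca lipid transporter genes 9 rose and 2 fell (median 1.16, camera adjusted p = 0.134), and of 18 Kctd genes 13 fell and 2 rose (median -0.52, camera adjusted p = 0.134). Of 21 keratin genes 14 rose and 2 fell (median 0.28, camera adjusted p = 0.15), and of 56 Eif translation initiation factor genes 32 fell and 12 rose (median -0.13, camera adjusted p = 0.264). All 5 missed the threshold after adjustment, with adjusted p = 0.909 with an estimated correlation.

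Of the 10 splits of the 6 libraries, 1 gave as many changed genes, the real split with 11732; the highest of the other 9 was 0 by edgeR and by limma-voom, with at most 94 genes at an unadjusted p under 0.05. With 10 splits the share cannot be under 0.05. The other 9 each mix CSC and non-CSC libraries in both groups, so the difference between CSC and non-CSC counts there as spread. A count near 0 in them is thus no measure of false calls.

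Median fold changes differed between chromosomes. The median log2 fold change was -0.34 over 615 genes of chromosome 12, -0.24 on chromosome 19, -0.17 on chromosome 14 and -0.14 on chromosome 3, and 0.21 over 1089 genes of chromosome 1, while within groups no library shifted the median of chromosome 12 by more than 0.012. Against a GC content or length bias, the chromosome 12 median lay -0.37 from that of all genes after the offset, and against chance placement, 0 of 10000 shuffles among genes of like expression put any chromosome as far out, the farthest at 0.113 against 0.347. A candidate explanation is a difference in DNA copy number between the cell populations. It would predict a shift along chromosome 12, and 85% of its 20 windows of 30 genes were lower by 0.1 or more. With so low a median, most windows would tend to be lower in a random order of the genes too. The tally thus cannot tell copy number from regulation spread along the chromosome. The order of the windows, which was not tested, was uneven. Windows 1 to 3 of chromosome 12 lay at 0.059, -0.032 and -0.085 from the median of all genes. Windows 4 to 20 all lay between -0.256 and -0.664. Such a run of adjacent windows is what a copy number difference of a segment would give, but regulation of a whole stretch could look alike. On chromosome 19, 18 of 21 windows were lower, and on chromosome 14, 15 of 19, just under the 80% set for chromosome 12. On chromosome 1, 29 of 36 windows were higher by 0.1 or more and 1 was lower. Only part was lower on chromosome 3, 16 of 28 windows with 4 higher, and on chromosome 5, 16 of 36 with 7 higher. Adjacent windows were again low together, windows 1 to 7 of chromosome 3 (-0.228 to -0.533) and 21 to 32 of chromosome 5 (-0.156 to -0.416). DNA was not analysed here, and regulation that differs between CSC and non-CSC stays open and untested.

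Counts assigned to Xist and to Tsix were far higher in CSC. Where these genes overlap, their reads are not separated without strand. A net fall of X output in CSC is argued against, since the median of 503 other X-linked genes lay above that of autosomal genes. The difference was 0.109 (SE 0.05), with 218 genes higher and 126 lower. Medians of other chromosomes lay as far out, such as 0.21 on chromosome 1 and -0.34 on chromosome 12. X inactivation itself is thus not decided, since a difference in X copy number could hide a fall in output. Host macrophages, fibroblasts and neutrophils in the CSC libraries are argued against as the source. C1qa, C1qb, C1qc, Tyrobp, Col1a1, Col1a2 and Col3a1 together reached at most 1.255 CPM in a CSC library, while Xist stood at 206 CPM. The neutrophil transcripts S100a8 and S100a9 reached at most 0.295 CPM together. Dcn, a fibroblast marker, goes the other way with 1212 CPM in CSC, but it also stood at 567 CPM in non-CSC. The median of all 20 tested markers of other cells was 0.65 (SE 0.515). Without the neutrophil markers Lcn2 and Ly6g, that of 18 was 0.499 (SE 0.351). These medians decide nothing, and other host cells are not covered by the transcripts above. Male cells in the non-CSC libraries are argued against by the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, with a summed 0 CPM. A biological difference between CSC and non-CSC may underlie the rise, as a hypothesis that was not tested further.

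Sema3c rose by 1.99 on the log2 scale, while a shift of the whole region around it by as much is argued against by its neighbours. Of the 5 protein-coding genes on each side 3 were tested, with a median of 0.28. Cacna2d1 rose by 0.48 (SE 0.117, edgeR adjusted p = 0.000988) and Phtf2 by 0.28 (SE 0.074, edgeR adjusted p = 0.00207), far less than Sema3c. Magi2, with only 78 counts over the 6 libraries, lay at -0.57 (SE 0.382, edgeR adjusted p = 0.193). The median of chromosome 5 was -0.06, but it mixes unlike parts, with 16 of 36 windows lower by 0.1 or more and 7 higher. The window of 30 tested genes that holds Sema3c, from 8396969 to 21488271, had a median -0.12 from that of all genes. Cacna2d1 ends at 16374511 and Phtf2 starts at 20758664, so a change limited to the stretch between them, of DNA or of regulation, stays open.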
